A study of Drosophila melanogaster with 10 samples.

How the data were processed

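ChIP-seq reads from 5 Twist precipitations and 5 input DNAs of Drosophila melanogaster embryos were used as the authors deposited them, as 1 line per aligned read with its chromosome, start, end, name and strand. Per the submitters' processing notes, reads were aligned with Bowtie to dm3. The version, the settings and any filter are not given in the sources used here. The deposited score column held 255 on every line and was not used. All reads of a set had 1 length: 36, 40, 40, 40 and 18 bp in Twist sets 1 to 5 and 36, 36, 40, 40 and 18 bp in the inputs. Per the labels' protocols, inserts of about 50, 75 and 100 bp were cut as gel slices about 25 bp thick. Which slice gave which library is not stated, and the insert number of the label (107, 72 or 49) was used; the libraries with the largest number are called long-insert.

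Groups and numbers came from the sample titles. Sets 3 and 4 of both groups shared read names. On the chromosome arms 24961115 Twist pairs and 24540377 input pairs of the same name lay on opposite strands within 500 bp, or 96.7% and 95.8% of the smaller set. Twist set 3 and input set 4 gave 80 such pairs on 2L. Sets 3 and 4 were therefore summed and counted as 1 library, which left 8 libraries in 2 groups of 4. Both mates of a pair were kept as reads, so the depth of this library counts each fragment up to 2 times. Distinct fragments made up 36.3% of the Twist pairs and 95.5% of the input pairs.

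Reads on 2L, 2R, 3L, 3R, 4 and X were moved toward the 3′ end by 50% of their insert number, rounded down, and counted in 200-bp bins. Counts were scaled to the arm reads of each library (RPM). This scaling lowers the background of a library in which many reads fall in bound regions. All reads were kept, repeated starts included, so amplification copies raise the counts of strong sites. Bins with a mean under 0.25 RPM over the 8 libraries were left out. The deposited values are read positions and not counts per feature, so log2(RPM + 0.5) was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with the group as the only term. Fold changes are on this scale, which understates the change of low bins. Bins were bound at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold of at least 1, and input-enriched at a log2 fold of -1 or less. Bound bins were joined across gaps of at most 200 bp. The summit was the highest pooled density of Twist read centres, smoothed over 31 bp. The pool was not weighted by library, so most of its reads came from the 72-bp library.

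The regions named in the text were the 12 with the highest log2 fold in which every Twist library lay above every input and the input mean was at least 0.5 RPM, and the 3 called bins with the lowest log2 fold. This rule, the tests and most alternatives were fixed before the data were examined. The merging of the mates was fixed then as a rule for sets that share reads. The comparisons of 2-summit regions, of enrichment per library and of insert sizes in limma, and those of distances between summits and of the heterochromatic contigs, were added later.

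Resolution was measured at the 500 bound regions of highest fold, with each Twist library thinned at random to the depth of the shallowest. This was 4025260 reads where 1 read per start was kept, and all reads were also thinned to that depth. Repeated starts were removed from the full libraries before thinning. The share removed therefore depended on the full depth, which was highest in the 72-bp library (51718217 reads). Read ends were taken within 400 bp of the pooled summit. Coverage was that of reads extended to the insert number. Its width at 50% of the maximum was read from the highest point within 100 bp of the summit, with 95% intervals from 1000 bootstrap draws over regions. A region had 2 summits where, within 300 bp, a second maximum of at least 50% of the first lay at least 60 bp away, with a valley of at most 75% of the lower one between them, and the highest coverage was at least 20 reads. Strand offsets were the lag, from 10 to 160 bp, with the highest correlation of plus and minus ends, counted with both ends included. Genome-wide, each start was used once and chromosome 4 was left out.

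Peaks of single libraries were 200-bp bins with an adjusted p under 0.01 in a one-sided Poisson test and at least 3 times the background. The background was the largest of the genome mean and the scaled input in the bin, in 1 kb and in 9.8 kb, where a window of 10 kb had been planned: a window centred on a bin spans an odd number of bins. Neighbouring bins were joined, all libraries were thinned to 5477864 reads (4025260 after 1 read per start had been kept), and an overlap of 1 bp counted. The stricter threshold was an adjusted p of 0.0001 and 5 times the background. Such tests take reads as independent, which copies are not. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for all other steps.

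The bin test was checked on simulated data for the Twist and input comparison with the real library sizes (560020 bins tested). Of 50 bins raised to each level, it recovered 8% at 2-fold, 92% at 4-fold and 100% at 8-fold and 16-fold, with 1 false call. All simulated libraries shared the mean input profile and 1 dispersion (0.0586), taken from the median spread of the inputs. Real Twist libraries varied more at the strongest regions, so these rates do not carry over to the real data. Simulated sites of known insert length gave offsets of 106, 106, 69 and 47 bp for 107, 107, 72 and 49 bp. They had 2 summits in 0% of single sites and at least 99.6% of pairs 150 bp apart. No closer pairs were simulated, although the real median spacing in the 49-bp library was 109 bp without thinning. The simulated background was uniform. These rates therefore do not show how well each insert size separates close sites.

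Alternatives covered the scaling, pseudocount, low-value filter, copies, read shift, bin width, spread model, pairing, left-out libraries, insert sizes, mates, thresholds and depth, and their effect is given in the closing section. Gene annotation and genome sequence of dm3 were not used here. The 13 gene lists and 14 motifs fixed beforehand, and the distance from summits to Twist binding motifs, were therefore not analysed, and regions are given by coordinates alone. Reads on the 6 heterochromatic contigs were left out of the comparisons and are described in the closing section.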

Results

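Binding of Twist to the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole wild-type Drosophila melanogaster embryos of the Oregon R strain, aged 2 to 4 h after egg laying. Twist is a basic helix-loop-helix transcription factor that is required for the formation of the mesoderm. The data were 10 sets of aligned reads, 5 from DNA precipitated with an antibody against Twist and 5 from input DNA, which is total chromatin DNA without precipitation. Inserts had been cut from a gel at about 50, 75 and 100 bp, and each label carries an insert number in bp, of which there were 3. In both groups the sets numbered 3 and 4 were the 2 mates of 1 paired-end library and were counted as 1 sample. Each group therefore held 4 libraries: 2 with the longest insert number, called the first and second long-insert library here, 1 with the number 72 and 1 with 49. Nothing in the labels says that the libraries came from separate embryo collections, so p-values measure only the spread between these libraries.

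The Twist libraries held 5477864 and 10510315 reads on the chromosome arms (first and second long-insert library), 51718217 (72-bp library) and 5977445 (49-bp library). The input libraries held 6643912, 7663321, 51388796 and 6532965 in the same order. Distinct combinations of start and strand numbered 85.4%, 66.6%, 30.2% and 67.3% of the arm reads in the Twist libraries and 95.7%, 93.2%, 73.6% and 93.8% in the inputs. Depths were not matched: the mate sets of the 72-bp Twist library alone gave 39.8% and 39.5%. The label of the first long-insert input names the Twist antibody, while its title names input DNA. In regions called without that pair of libraries, its reads were 2.07-fold over the share of bases, against 15.9-fold in the first Twist library. This was the highest value of the inputs: the others gave 1.54, 1.62 and 1.66-fold, each in regions called without its own pair.

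The comparison of Twist with input asks where in the embryo's genome Twist was bound. Twist reads were concentrated at 5362 regions of the 6 chromosome arms, made of 8935 bound bins of 200 bp among 551904 tested. In the strongest bin, on 2L at 20486201 to 20486400 (dm3), Twist libraries held 343 ± 205 RPM (reads scaled to the depth of the library) and inputs 3.39 ± 1.11 RPM (SD, n = 4 each). Most regions were weaker, with a median log2 fold of 1.66 on the log2(RPM + 0.5) scale at their best bin. A log2 fold of at least 2 was reached by 1739 regions and of at least 3 by 474. The median region was 200 bp wide, 112 were wider than 1000 bp, and the widest covered 3400 bp of 3L (16766001 to 16769400). In 4843 regions (90.3%) every Twist library lay above every input at the best bin. Chance alone separates 4 from 4 libraries in this direction in 1.43% of cases, and 2.71% of all tested bins were separated. Since the best bins were chosen by a test on the same libraries, this share is not independent evidence of binding.

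Bound bins passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05 with a log2 fold of at least 1. The number of calls rested on both long-insert pairs: without the first pair of libraries 4849 bins in 3047 regions were called, and without the second 3889 bins in 2473 regions. The second long-insert input stood apart, with Pearson correlations from 0.343 to 0.512 with the other libraries, against 0.608 to 0.860 among the rest (log2 RPM of bins). The long-insert libraries alone gave 14389 bound bins, while the 72-bp and 49-bp libraries alone gave 0 with limma (38196 bins at an unadjusted p under 0.05).

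Bound regions held 12.7 ± 3.74% of the arm reads of Twist libraries and 2.57 ± 0.316% of those of inputs (SD, n = 4 each). Relative to the share of bases, this was an enrichment of 11.6, 7.74, 7.58 and 5.88-fold in the first long-insert, second long-insert, 72-bp and 49-bp Twist libraries, and of 1.94, 1.48, 1.64 and 1.56-fold in the inputs. With 1 read per start it was 9.04, 6.19, 4.21 and 5.14-fold in the Twist libraries, and 6.47-fold in the 72-bp library with distinct fragments. The 95% Wilson intervals of the shares in single libraries reach at most 0.0322 percentage points to either side. They take each read as independent, which copies of 1 molecule are not, so they are too narrow even for counting error. They cover no other error. Regions called without a library's own number gave a measure free of that library's calls. There, reads were 9.83 ± 4.72-fold over the share of bases in Twist libraries and 1.72 ± 0.239-fold in inputs (SD, n = 4 each). Same-numbered Twist and input libraries were scored on the same regions, called from the other libraries by group. Their values are therefore not free to be exchanged between groups, and no p-value is given. Each Twist library lay above each input, from 4.77-fold in the 49-bp library (over 7600 regions) to 15.9-fold in the first long-insert library (over 3047). The region sets differ between library numbers, so these values compare Twist with input and not one insert size with another.

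The 12 regions named by the rule fixed beforehand lay on 2L (4 regions), 3R (3), 2R (2), 3L (2) and X (1). The strongest was at 20486001 to 20486800 on 2L, with its summit at 20486283 and a log2 fold of 6.30 ± 0.85 (SE; limma adjusted p = 1.19e-05). Another of the 12 lay close beside it at 20481001 to 20481600 on 2L, with 160 ± 72.8 RPM in Twist against 2.92 ± 0.756 in input. The second by fold was at 15485601 to 15487000 on 2L, with 262 ± 96.9 RPM in Twist against 3.91 ± 0.921 in input. On 3R, the region at 8895801 to 8896400 held 233 ± 119 RPM against 3.64 ± 1.25. The region at 788401 to 788600 on 3R was a single bin, in which Twist libraries ranged from 43.0 RPM (49-bp) to 315 RPM (72-bp). On 3R at 17870201 to 17870800, Twist libraries held 136 ± 38.4 RPM, with the first long-insert library at 194 RPM and the other three between 114 and 118 RPM.

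On 2R, the region at 18295801 to 18296400 held 246 ± 143 RPM in Twist against 4.62 ± 1.49 in input, and the region at 5818801 to 5819600 held 156 ± 88.1 against 2.73 ± 0.647. On 3L, the region at 741601 to 743600 was the widest of the 12 at 2000 bp, with 165 ± 82.7 RPM against 2.47 ± 0.879, and the region at 1461601 to 1462800 held 138 ± 72.2 against 2.85 ± 0.741. The region at 4370001 to 4370400 on 2L held 142 ± 51.9 RPM against 2.47 ± 0.414. The X region, at 486601 to 487200, held 139 ± 48.02 RPM against 2.89 ± 0.313. Over the 12, the log2 fold ran from 5.26 to 6.30 and the limma adjusted p from 2.43e-07 to 7.86e-05. With 1 read per start all 12 still passed, with log2 folds from 3.23 to 3.90 (highest adjusted p = 0.00107). The spread between Twist libraries was wide, so the order of the 12 is not resolved by these libraries. None of the 12 passed limma's test in the 72-bp and 49-bp libraries alone, where their log2 folds ran from 4.78 to 5.99 (lowest adjusted p = 0.0762). Without the second long-insert pair, 4 did not pass (2L at 20486001 and 15485601, 3R at 8895801 and 2R at 18295801; lowest adjusted p = 0.132), with log2 folds from 5.38 to 6.31. The last of these also did not pass without the 72-bp pair (log2 fold 5.37, adjusted p = 0.0529).

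**Figure D1:**
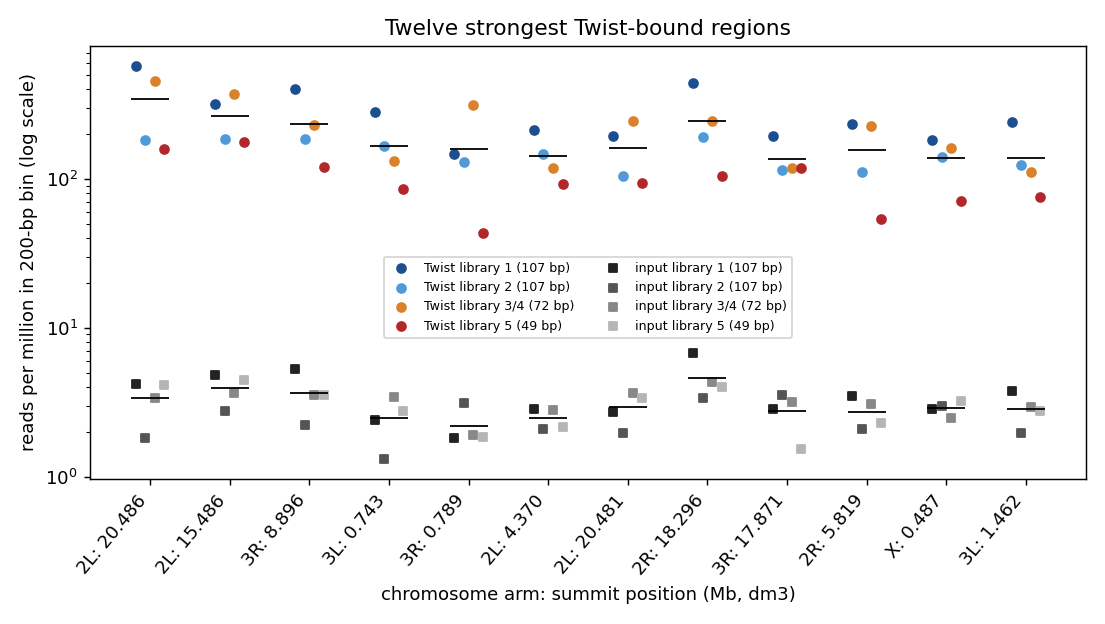
RPM (log axis) in the best 200-bp bin of the 12 named regions, placed by the dm3 position of their summits; circles are Twist libraries, squares input libraries, and horizontal bars group means of 4 libraries. Twist libraries sit between 43.0 and 575 RPM, all above the inputs, which sit between 1.30 and 6.77 RPM.

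Bound regions were spread over the large arms at similar density, and fewer per Mb were called on chromosome 4. The median log2 fold of all tested bins was also lower there, at -0.652 against -0.394 to -0.276 on the other arms. Per Mb of tested bins there were 52.1 regions on 3R (95% exact Poisson interval 49.4 to 54.9), 50.8 on 2R (47.6 to 54.0), 45.5 on 3L (42.7 to 48.3) and 45.0 on 2L (42.2 to 47.9). X had 1013 regions, with an interval of 47.9 to 54.2 per Mb. Chromosome 4 had 16 regions, or 14.3 per Mb (8.17 to 23.2). Its density was 0.292 times that of the other arms (two-sided exact binomial test, p = 1.99e-09), and 0.112 times among regions with a log2 fold of at least 2, where it had 2 (p = 6.45e-06). These tests treat regions as independent. Some stretches held many regions: 16 summits lay in the 50 kb of 3R from 900001 to 950000, where the strongest had a log2 fold of 4.85, and 15 lay in 3R 650001 to 700000. Windows with 14 summits were found at 2R 15150001 to 15200000, X 19650001 to 19700000, 3R 15150001 to 15200000 and 3R 2550001 to 2600000.

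**Figure D2:**
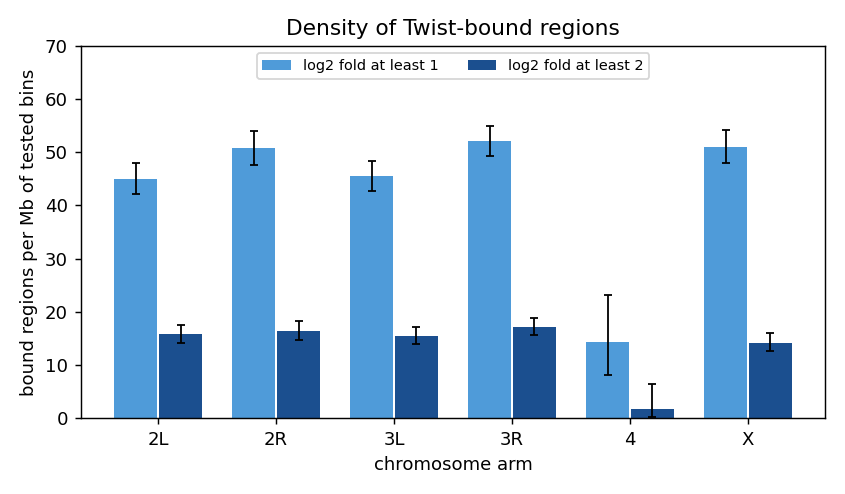
Bound regions per Mb of tested bins on each chromosome arm at both fold thresholds; bars start at 0 and error bars are 95% exact Poisson intervals. Chromosome 4 lies at 14.3 and 1.79 per Mb, below the other arms, which lie between 45.0 and 52.1 and between 14.2 and 17.2.

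In the other direction, 9842 bins were higher in input at a log2 fold of -1 or less. They made up 4.04% of tested bins on chromosome 4, 0.976% on X and between 1.70% and 2.10% on the other arms, and under the background scaling described below 1.16%, 0.257% and 0.450% to 0.593%. The lowest called bins were at 23565401 to 23565600 on 3L (log2 fold -3.14; 10.9 ± 9.87 RPM in Twist, 93.5 ± 70.3 in input), at 8253201 to 8253400 on X (-3.07; 1.21 ± 0.874 against 32.4 ± 50.1) and at 7798001 to 7798200 on X (-3.06; 0.436 ± 0.510 against 48.4 ± 88.8). On X the input SD exceeded the input mean in both bins. The median log2 fold of all tested bins was -0.34, and -0.16 when libraries were scaled to 10-kb windows without a bound bin, a shift of 0.17. Of all bound and input-enriched bins, 47.6% were bound as reported and 80.1% under that scaling. All 8935 bound bins remained bound under it, but only 2706 of the input-enriched bins stayed so. That scaling set library sizes to 0.670 to 0.848 of the arm reads in Twist and 0.913 to 0.961 in input. It thus raised the folds of Twist over input, which favours bound bins and works against input-enriched ones. The difference between the 2 classes is therefore no test of either. Without the first, the second, the 72-bp or the 49-bp pair the input-enriched bins numbered 472, 75, 2364 and 52158, and they numbered 96 with a pseudocount of 2 RPM and 131176 with voom, so this count is not stable.

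The title names high resolution, and the sized gel slices allow a comparison of inserts of different length. The distance between plus-strand and minus-strand read ends followed the insert number in the Twist libraries. Over the whole genome it was 102 and 105 bp in the long-insert libraries, 72 bp in the 72-bp library and 48 bp in the 49-bp library. The inputs gave 73, 94, 60 and 45 bp. Mate pairs of the 72-bp library gave insert lengths directly: a median of 72 bp in Twist (mean 72.6 ± 12.5 bp, SD over 24961115 pairs) and 65 bp in input (65.9 ± 13.8 bp, 24540377 pairs). At the 500 regions of highest fold, with each Twist library thinned to 5477864 reads, the offset was 96 bp in the first long-insert library, 68 bp in the 72-bp library and 47 bp in the 49-bp library; in the second long-insert library it was 104 bp at 200 regions, 106 bp at 1000 and, without thinning, 100 bp at 500.

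**Figure D3:**
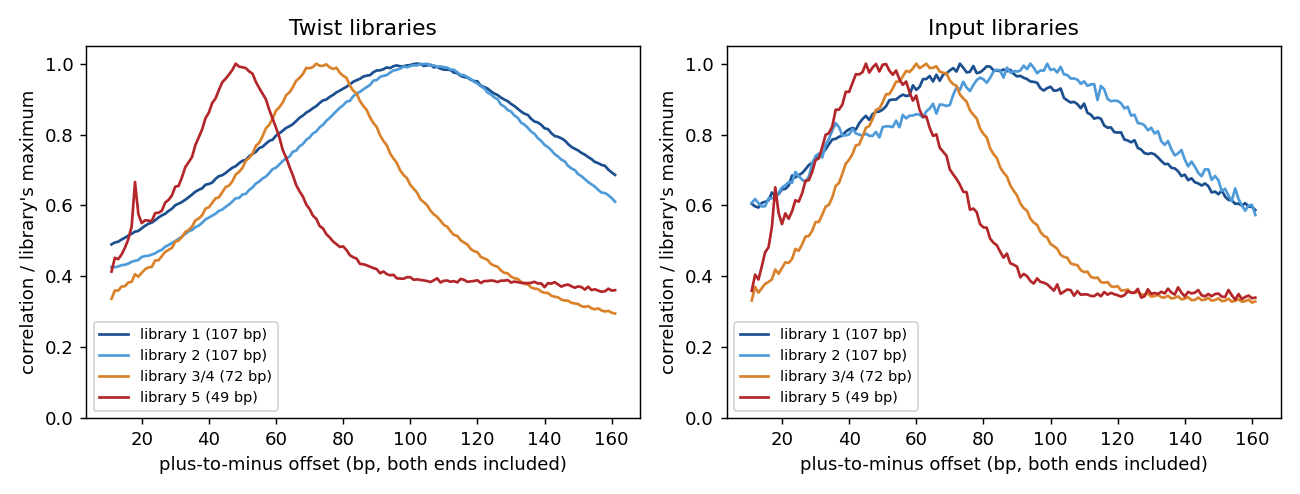
Correlation of plus-strand and minus-strand read starts against their offset in bp, divided by each library's own highest value, for Twist (left) and input libraries (right). Twist curves peak at 102, 105, 72 and 48 bp for the first long-insert, second long-insert, 72-bp and 49-bp libraries.

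Coverage at the 500 strongest regions was narrower in the libraries of shorter inserts. The median width of the coverage at 50% of its maximum was 137 bp (95% bootstrap interval over regions 132 to 141) and 141 bp (135.5 to 145) in the long-insert libraries, or 139 ± 2.83 bp (SD, n = 2). It was 88 bp (86.5 to 90.5) in the 72-bp library and 74 bp (72 to 76.5) in the 49-bp library. With 1 or 2 libraries per insert size, no test between sizes was made. Read length differed too, at 18 bp in the 49-bp library against 36 or 40 bp in the others. The order depended on the extension: with all reads extended to 72 bp the widths were 119.5, 122, 88 and 120 bp. With 1 read per start and strand, kept before thinning to 4025260 reads each, they were 168.5, 170, 154 and 98 bp, and 155, 152, 154 and 150.5 bp if also extended to 72 bp. At that depth with copies kept they were 136, 140.5, 88 and 72 bp. Distinct fragments at that depth gave 103.5 bp in the 72-bp library. Median distances between the summits of the libraries ran from 14 bp (both long-insert libraries) to 24 bp (first long-insert against 49-bp library). Each summit was sought only within 100 bp of the pooled summit from the same reads, which limits these distances in advance.

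More of the 500 regions showed 2 separate summits in the libraries of shorter inserts. In the long-insert libraries 73 regions (14.6%, 95% Wilson interval 11.8 to 17.96) and 87 regions (17.4%, 14.3 to 20.97) did. The 72-bp library had 146 (29.2%, 25.4 to 33.3), and the 49-bp library 318 of 498 with enough reads (63.9%, 59.5 to 67.95). The median spacing of the 2 summits was 198 and 201 bp in the long-insert libraries, 160.5 bp in the 72-bp library, and 109 bp in the 49-bp library without thinning. In 50 regions both long-insert libraries had 2 summits, against 12.7 for independent lists, and the 72-bp and 49-bp libraries shared 120, against 92.9. Median coverage at the summit differed, at 291, 182, 153 and 72 reads. With 1 read per start and strand at 4025260 reads, the 72-bp library had 325 such regions and the 49-bp library 362, against 142 and 305 at that depth with copies kept. With distinct mate-pair fragments at that depth the 72-bp library had 185. Keeping 1 read per start also drops different fragments that share a start. It was done on the full libraries before thinning, so it removed a larger share from the deeper 72-bp library. The comparison at equal depth therefore does not isolate the effect of copies.

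**Figure D4:**
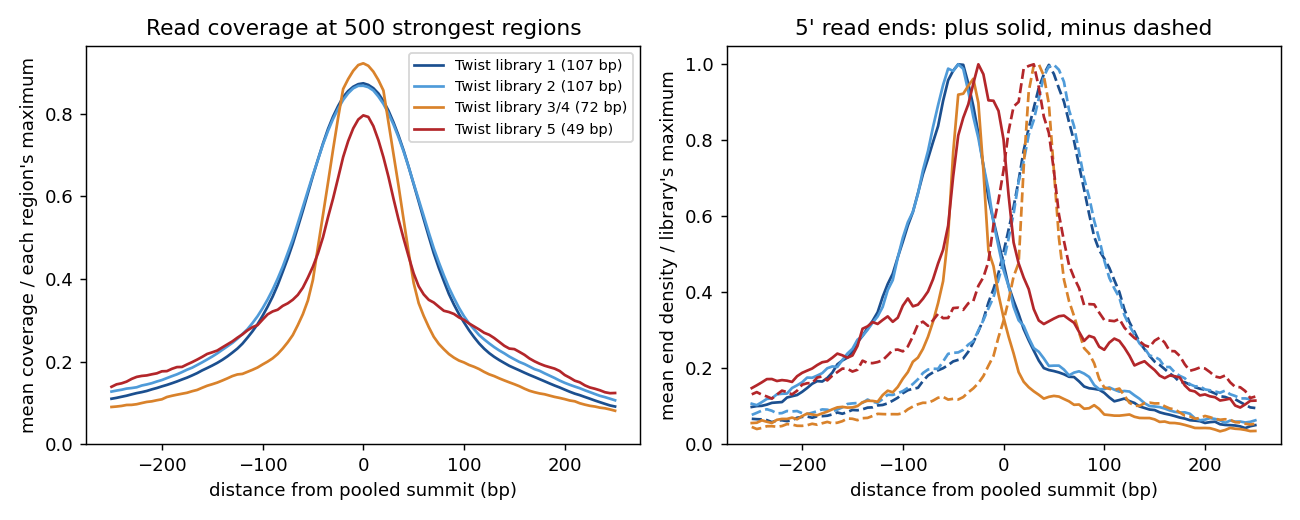
Left, mean read coverage around the pooled summits of the 500 strongest regions, relative to each region's highest value; right, mean density of 5′ read ends (plus strand solid, minus strand dashed) relative to the library's highest value; both against distance from the summit in bp, for the 4 Twist libraries. Strand peaks lie closer together in the 72-bp and 49-bp libraries, whose offsets at these regions were 68 and 47 bp, than in the long-insert libraries (96 bp in the first); most reads behind the pooled summits came from the 72-bp library.

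Each Twist library was also compared with its same-numbered input at 5477864 reads, to ask how far the libraries call the same sites. This gave 5792 and 7376 peaks in the long-insert libraries, 6572 in the 72-bp library and 3363 in the 49-bp library. Of the peaks of the first long-insert library, 68.3% overlapped one of the second, 49.8% one of the 72-bp library and 35.8% one of the 49-bp library. Of the peaks of the 49-bp library, 60.8% overlapped one of the first long-insert library. Of 12648 peaks in the union, 1626 were seen in all 4 libraries and 7369 in 1. At a stricter threshold 3837 were left, of which 644 were seen in all 4 libraries. These tests compare single libraries, not conditions, and the 72-bp library had 2939 peaks with 1 read per start at 4025260 reads, against 6950 at that depth with copies kept. Repeated starts were removed before thinning, so these counts differ in more than copies.

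Whether the fold of Twist over input differed between the long-insert libraries and the shorter ones was tested as an interaction in limma. No bin of 551904 passed an adjusted p of 0.05, while 48070 had an unadjusted p under 0.05. With 1 read per start and strand, 99 of 555452 bins passed (75395 at an unadjusted p under 0.05). Of these, 84 had a higher fold in the shorter inserts and 15 a lower fold. Where nothing differs, a share of about 0.05 of the bins is expected at an unadjusted p under 0.05. Both unadjusted counts lie above that share, so the lack of passing bins with all reads does not show equal folds. For the 12 named regions the difference in log2 fold ran from -1.66 ± 0.93 (SE; 3L at 741601, limma adjusted p = 0.617) to 0.10 ± 0.92 (3R at 17870201, limma adjusted p = 0.982), and none passed.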

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

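The tests of the 2-summit regions, of enrichment and of the heterochromatic contigs were chosen after the data were seen. For 2-summit regions, the criterion for stacks of reads with the same start was written after its value was seen. The criteria for enrichment were changed after their values were seen. The counts over splits were set before they were run. Among 36 groups of 4 libraries, 3 held a library far from the rest by Dixon's test, which chance alone does in about 1 group in 20. The second long-insert input correlated with the other libraries at 0.343 to 0.512, against 0.608 to 0.860 among the rest, and without its pair 3889 bound and 75 input-enriched bins were called. In input, distinct starts numbered 73.6% of the reads in the 72-bp library, against 93.2% to 95.7% in the others. This library was also the deepest, at 51388796 reads from 2 summed mate sets. Its mate sets alone gave 83.7% and 83.8%, and distinct fragments made up 95.5% of its pairs. In the named region at 788401 to 788600 on 3R, the second long-insert input held 3.13 RPM, against 1.81 to 1.91 in the other inputs. In the region at 17870201 to 17870800 on 3R, the first long-insert Twist library held 194 RPM, against 114 to 118 in the other Twist libraries. Outside the chromosome arms, 10 of 23022 tested bins on heterochromatic contigs were bound in Twist over input by the same limma test. The strongest lay on 2RHet at 1266401 to 1266600, with 18.3 ± 8.30 RPM against 2.22 ± 0.566 (SD, n = 4; log2 fold 2.71, limma adjusted p = 0.001).

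For each of the 3 counts of called bins and regions, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave a count that large. This is the smallest share that 35 splits allow, so chance is unlikely for these counts but not excluded. The real split gave 8935 bound bins against at most 305 in another split, 5362 bound regions against at most 296, and 9842 input-enriched bins against at most 305. All other splits mix Twist and input within groups, which widens the spread there, so the size of the gap is not a measure of evidence. Without the second long-insert pair only 75 input-enriched bins were called.

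The 49-bp Twist library had 2 summits in 63.9% of regions. Lower read coverage at its summits does not account for this alone, since at equal median coverage the highest share in another Twist library was 31.5%. Copies were kept there and each library had its own extension. Coverage by distinct reads was not matched, so low distinct coverage, alone or with the extension, stays open. The shorter extension of the 49-bp library accounts for part at most. With reads extended to 72 bp its share was 49%, still above the 29.2% of the 72-bp library. Stacks of reads with the same start stay open. With 1 read per start the share was 74.5%, but the same step raised the 72-bp library from 29.2% to 65.9% and cut its median summit coverage from 153 to 32 reads, so it decides nothing. At the same 4025260 reads with copies kept, the 72-bp library had 28.4% (142 regions), and with distinct fragments 185 regions. A finer separation of neighbouring binding sites by short inserts remains a hypothesis, with which the 49% at equal extension is compatible. With 1 library of this size, properties of the library itself stay open too. Among them is read length, which was 18 bp there against 36 or 40 bp in the other Twist libraries and was not tested.

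Enrichment in bound regions was 11.6-fold and 7.74-fold in the long-insert Twist libraries, 7.58-fold in the 72-bp library and 5.88-fold in the 49-bp library. Copies stay open: with 1 read per start the ratio to the 49-bp library was 1.76 in the first long-insert library but 1.203 in the second, and the 72-bp library fell below the 49-bp library (4.21 against 5.14; 6.47 with distinct fragments). Background shared with input stays open too, since after division by the same-numbered input the ratio went from 1.97 to 1.58 in the first long-insert library and was 1.39 in the second. Both met the bound of 1.5 written for the first library alone, which ignored that libraries of 1 size differ about as much. Insert size and library preparation cannot be told apart either, because sizes below the largest had 1 library each. Nor can insert size and read length in the 49-bp library, whose reads were 18 bp long against 36 or 40 bp in the others. The 2 long-insert libraries differed by a ratio of 1.496, against 1.02 between the second of them and the 72-bp library; under the first wording of the criterion this counted against insert size. It was reworded because it says nothing of the 49-bp library.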

How the results depend on the processing

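The counts for mates, distinct fragments, size-class bins, 2-summit regions, equal coverage, equal depth with copies kept, enrichment per library, regions under the other scaling, and for input-enriched bins with voom, the block, fragments or a library pair left out were chosen after seeing the data. Bound bins stayed within 1.5 times of 8935 under the other scaling, both pseudocounts, both filters, copies removed and measured read shift. They also did so with voom, high-input bins left out and the 4 settings for mates and copies. Counts at other bin widths are not comparable, since the bins cover unlike lengths. Bound were 10648 of 1063473 tested bins of 100 bp and 4551 of 227396 of 500 bp, against 8935 of 551904 of 200 bp. The 72-bp and 49-bp libraries alone gave 0 bound bins (38196 at an unadjusted p under 0.05 in limma). Bound 200-bp bins numbered 14389 with the long-insert libraries alone and 2609 at a log2 fold of at least 2. With 1 library pair left out they ranged from 3889 (second long-insert pair) over 4849 (first) to 11958, and regions from 2473 to 7600. At a log2 fold of at least 2, 1777 regions were formed. Of the 8935 bound bins, 8181 remained with 1 read per start and 8451 with distinct fragments. Input-enriched bins, 9842 as reported, numbered 2706 under background scaling, 2508 and 96 with pseudocounts of 0.1 and 2 RPM, 4081 with 1 read per start, 4074 with distinct fragments, 131176 with voom and from 75 (second long-insert pair) over 472 (first) and 2364 (72-bp) to 52158 (49-bp) with 1 pair left out. Bins that differed between insert sizes went from 0 to 99 with 1 read per start. Apart from the smaller number of bins or samples, the cause was not tested. For the 12 named regions, 240 values were computed under alternatives: 0 reversed, 17 no longer passed the threshold, and the log2 fold ran from 3.23 (1 read per start) to 6.70 (without the 49-bp pair). Of the 17, 12 came from the 72-bp and 49-bp libraries alone.

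Same-numbered Twist and input libraries deviated from their group means with correlations of 0.22, -0.03, 0.17 and 0.03, so the numbers were not taken to pair the samples. Not every library correlated best with its own number: the second long-insert Twist library did so with the first input (0.20) and the 49-bp Twist library with the second (0.26). A replicate block gave 10859 bound bins, which held all 8935, 6432 regions and 30943 input-enriched bins, and 10239 bound bins with 1 read per start.

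Widths of 137, 141, 88 and 74 bp became 168.5, 170, 154 and 98 bp with 1 read per start at 4025260 reads (136, 140.5, 88 and 72 bp at that depth with copies kept), and 119.5, 122 and 120 bp in the long-insert and 49-bp libraries with a common extension of 72 bp. In the long-insert libraries they were 133 and 134 bp at 200 regions and 134 and 136 bp at equal coverage, and distinct fragments gave 103.5 bp in the 72-bp library. Strand offsets stayed within the spread of the long-insert libraries. The 72-bp library had 325 regions with 2 summits with 1 read per start, and 185 with distinct fragments. Peaks per library were 2595, 2170, 1907 and 1268 at the stricter threshold, and 2939 in the 72-bp library with 1 read per start (6950 at that depth with copies kept); mean overlap stayed within the spread over pairs of libraries. Gene lists, motifs and distances to motifs, and their alternatives, were not run.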

Other observations

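All tests of this part were chosen after the data were seen; the share of summits within 5 kb was known when they were written, the random placements were not. Bound regions lay close to each other along the arms. Of 5362 summits, 63.0% had another within 5 kb, and the median distance to the nearest was 2967 bp. In 1000 random placements of as many summits on the tested bins of each arm, the share ran from 34.6% to 39.5%, so random placement does not account for it. Nor does the splitting of regions within 1 kb. With summits within 1 kb counted as 1, 55.8% of 4919 summits had another within 5 kb, against 26.4% to 31.3% in random placements. The random summits were merged in the same way after they were drawn, so they were somewhat fewer. Broader regions that were called in parts are not excluded. That Twist sites occur in clusters of separate sites is a hypothesis from these data. Random placement ignores that open chromatin is itself clustered, which was not tested.

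On the heterochromatic contigs, the 10 bound bins lay on 2RHet (6 bins), 3LHet (2) and XHet (2). The bin at 1267201 to 1267400 on 2RHet held 19.0 ± 3.51 RPM in Twist against 2.84 ± 0.507 in input (SD, n = 4; log2 fold 2.54, limma adjusted p = 0.001). In the other direction 1498 of the 23022 bins were higher in input. These contigs took 3.19 ± 0.462% of the reads in Twist libraries and 5.41 ± 1.17% in inputs. The mitochondrial genome took 0.103 ± 0.0904% and 0.485 ± 0.497%. Chromosome 4 took 0.617 ± 0.0997% in Twist and 0.882 ± 0.157% in input, and X took 14.6 ± 0.550% and 14.4 ± 0.516%.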
